A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

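The series measured poly(A) RNA of vegetatively growing *Saccharomyces cerevisiae* of the SK1 strain, a laboratory strain known for efficient sporulation. Cells grew in rich medium and were harvested in exponential phase, per the labels' protocols. Directional mRNA libraries were made with a NEXTflex kit and read as 50-base single ends on an Illumina HiSeq instrument, per the labels' protocols. The 4 libraries form 2 groups of 2. The vehicle group holds ethanol controls volume matched to 20 nM and 40 nM of inducer, and the inducer group holds cells given 20 nM and 40 nM of a compound the labels call bEST. The labels do not spell out that name, and they give neither ploidy nor mating type. The labels do not say that the libraries of a group came from separate cultures. The p-values of genes therefore measure only the spread between these samples, which may be technical.

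The deposited table lists 6679 systematic gene identifiers and 1 value per library, with no unit in its header. The unit was taken as RPKM, reads normalised to gene length and library depth, as the authors' deposited values behave. Multiplied by the coding length less 60 bases, they were whole multiples of a fixed amount in each library. Of values of up to 50 reads, 92.8% to 93.7% lay within 0.05 reads of a whole number. The submitters' processing notes name STAR and SAMtools. The counting tool, genome build, annotation and any filter are not given in the sources used here. The steps gave depths of 2133000 reads (vehicle, 20 nM matched), 2599000 (vehicle, 40 nM matched), 1183000 (inducer, 20 nM) and 4161000 (inducer, 40 nM). The median gene had 96, 115, 52 and 196 reads in these libraries. Reads carry no molecular identifiers, so Poisson intervals of 95% cover counting error only.

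Gene symbols, coding lengths, overlaps and the share of 50-base windows repeated elsewhere in the genome came from the R64 reference. Of the 6679 identifiers, 5994 matched its locus tags and 685 did not, the latter holding at most 2.03% of the RPKM of any library. No coordinates are printed, because the build used for the values is not given. R64 is not the SK1 genome, so strain differences in sequence were not analysed here.

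The comparison of inducer with vehicle used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a trend of variance on level and no covariate, in genes with a mean of at least 5 RPKM. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and every adjusted p of a gene comes from this limma fit unless another is named. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Because the 2 libraries of a group differ in dose, any effect of dose counts as spread. The plan named count-based tests in case the table held counts. As the deposited values are RPKM, the plan's test for normalised values was the main one. Reads recovered with R64 lengths served for depth, counting error and an alternative fit with limma-voom, which was run after seeing the data. Gene lists, 29 in number, the rule for named genes and the alternatives were written before the data were examined. Lists with at least 5 tested members, 28 of them, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Its p-values set the genes of a list against other genes under that assumed correlation. Small ones therefore do not stand for agreement among many libraries. Beside this test stood fry and camera with an estimated correlation. The latter rests on the few libraries. At 2 against 2 it could hardly pass a list after adjustment, so its failure says little. The Galactose regulon list had 3 members above the filter and was not tested.

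Each dose has 1 library per treatment, so doses were described without a test, as the log2 ratio of each inducer library to its volume-matched vehicle. List medians were placed among 10000 random lists of the same size matched on mean level. Random lists were drawn from all tested genes, the list's own members included, which can pull percentiles of large lists toward the middle. Genes named are HAC1, KAR2, PDI1, ERO1 and INO1; the 10 largest rises and falls past the threshold with separated libraries and a mean of at least 10 RPKM; up to 4 members of each list past the threshold, or up to 2 as values where none passed; and the 5 genes each way with the largest difference between the dose ratios. Genes named outside this rule are said to be so. Gene Ontology terms with 5 to 300 tested members and experimental annotations in R64 were tested for enrichment by the hypergeometric test. That test was chosen after seeing the data, and its p-values count genes and not libraries.

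The test was checked on simulated data for the comparison of inducer with vehicle, with 5703 genes in 2 against 2 libraries. It recovered 79.1% of genes changed by 1 on the log2 scale and 100% of those changed by 2 and of those changed by 3. It called 0.248% of unchanged genes, and camera gave p under 0.05 in 2.8% of random lists. Simulated genes varied independently and with the same spread in both groups. These error shares therefore need not hold for lists of genes that vary together or for groups of unequal spread. The simulated spread, 0.186 on the log2 scale, was that of the vehicle pair above 100 RPKM. Over all tested genes the spread per library was 0.305 for the vehicle pair and 0.444 for the inducer pair. These values include counting error, which the simulation added to its 0.186. Among 916 genes with at least 200 reads in every library, the SD of the log2 difference was 0.199 within the vehicle pair and 0.529 within the inducer pair. With that wider inducer spread, the shares recovered lie above what holds for these data. Alternatives were other pseudocounts, filters, a median scaling, a volume block, dose as a number, HAC1 left out, a fold threshold and each library left out. In the volume block fit and the fits without a vehicle library, a common variance trend replaced each gene's own spread. A call lost there need not mean a changed fold change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.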

Results

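Poly(A) RNA was measured in 4 libraries of vegetatively growing SK1 yeast, 2 with vehicle and 2 with an inducer, to compare cells with and without exogenously driven spliced HAC1 mRNA. HAC1 encodes the transcription factor of the unfolded protein response, the programme that answers unfolded protein in the endoplasmic reticulum (ER). Recovered depth was 2133000 and 2599000 reads for the vehicle libraries matched to 20 and 40 nM. It was 1183000 and 4161000 reads for the inducer libraries at 20 and 40 nM, so counting error is largest in the 20 nM inducer library. Across genes, the vehicle libraries correlated at r = 0.981 and the inducer libraries at 0.957. The 40 nM inducer library correlated at 0.957 with the 20 nM vehicle library too, and the 20 nM inducer library at 0.925 and 0.932 with the vehicle libraries. Values are in the order vehicle 20 nM, vehicle 40 nM, inducer 20 nM and inducer 40 nM unless stated.

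HAC1 (YFL031W), the gene the study describes as driven, stood at 487 and 528 RPKM in the vehicle libraries and at 5922 and 3712 RPKM in the inducer libraries. Its log2 fold change was 3.21 (SE 0.26, adjusted p = 0.00211). Gene-level values do not separate spliced from unspliced HAC1 mRNA, or a driven copy from the native one. The labels give all libraries a wild-type genotype and do not say how HAC1 was driven. Poisson intervals, which cover counting error only, were 5753 to 6096 RPKM at 20 nM and 3640 to 3785 RPKM at 40 nM. The log2 difference between these inducer libraries, -0.67, was close to the SD of that pair across all tested genes, 0.63, and was not tested. Among 916 genes with at least 200 reads in every library, where counting error is small, that SD was 0.529. Known targets of the response rose with it. KAR2 (YJL034W), the ER Hsp70 chaperone, went from 354 and 395 to 4194 and 3612 RPKM (log2 fold change 3.38, SE 0.20, adjusted p = 0.00177). ERO1 (YML130C), the ER thiol oxidase, went from 176 and 142 to 1266 and 1465 RPKM (3.10, SE 0.23). PDI1 (YCL043C), protein disulfide isomerase, went from 343 and 422 to 1730 and 936 RPKM (1.74, SE 0.32, adjusted p = 0.0357), a call that ended without the 20 nM inducer library (adjusted p = 0.0535). INO1 (YJL153C), which makes inositol phosphate, stood at 0.91 and 1.75 RPKM with vehicle and 18.1 and 23.8 RPKM with inducer (3.25, SE 0.43, adjusted p = 0.0107), with 2.031 at a pseudocount of 5 and 3.932 at 0.1.

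**Figure D1:**
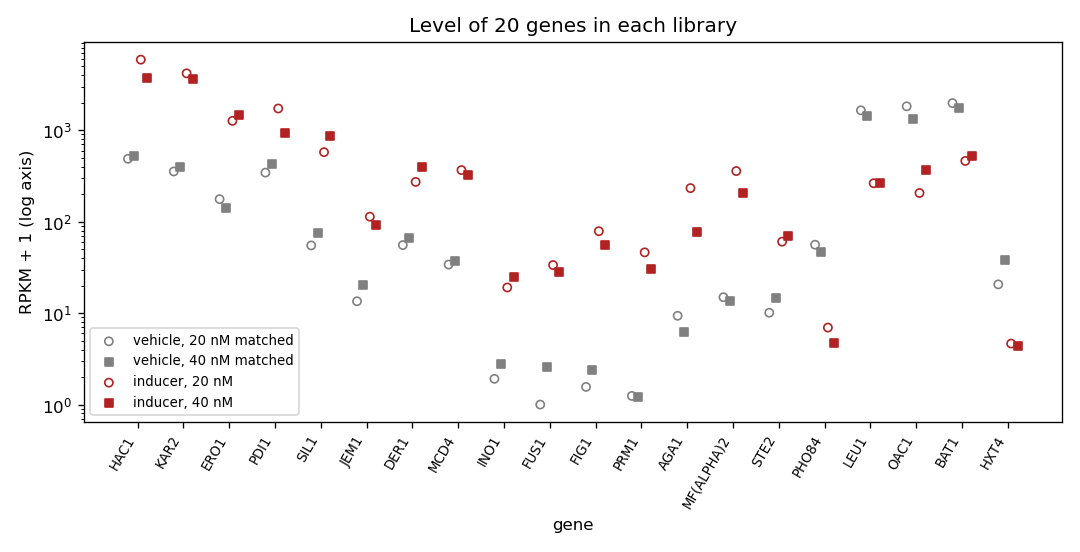
RPKM + 1 on a log axis for 20 genes in each of the 4 libraries, with grey for vehicle, red for inducer, open circles for 20 nM and filled squares for 40 nM. HAC1 lies at 487 and 528 RPKM with vehicle and at 5922 and 3712 RPKM with inducer, and no gene shown has overlapping groups.

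Across 5317 tested genes, 132 rose and 39 fell with the inducer, and 869 had an unadjusted p under 0.05. All 171 calls had both inducer libraries beyond both vehicle libraries, and so the same sign at both doses. Such separation held for 46.9% of all tested genes, where chance gives 33.3%. Of the 132 rises, 30 belonged to the 6 lists of ER folding, translocation, degradation, glycosylation and transport, which had 152 tested members. Another 78 rises and 32 falls lay in no list. Leaving out the 40 nM inducer library raised the counts to 333 rises and 460 falls.

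ER folding genes had the highest median of the 6 ER lists. Of 18 ER chaperones and folding enzymes 11 rose (12 adjusted over the list alone), with a median log2 fold change of 1.795 (camera adjusted p = 4.99e-11, adjusted p = 0.438 with an estimated correlation). SIL1, the nucleotide exchange factor of KAR2, went from 54.0 and 74.3 to 575 and 859 RPKM (3.45, SE 0.29). JEM1, an ER J-domain protein, changed by 2.63 (SE 0.27). Of 18 ER-associated degradation genes, which remove misfolded protein from the ER, 4 rose (7 adjusted over the list alone; median 0.49, camera adjusted p = 3.19e-05, adjusted p = 0.438 with an estimated correlation). These were DER1 (2.44, SE 0.26), DFM1 (1.996, SE 0.23), USA1 (1.96, SE 0.29) and HRD1 (1.29, SE 0.26), of which HRD1 lost its call without either vehicle library (adjusted p = 0.107 and 0.153) and USA1 without the 20 nM inducer library (adjusted p = 0.063).

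Protein modification genes rose in part. Of 26 genes of O-mannosylation and GPI anchors 6 rose (7 adjusted over the list alone; median 0.11, camera adjusted p = 0.00989, adjusted p = 0.438 with an estimated correlation). MCD4, a GPI anchor transferase, went from 33.0 and 36.6 to 366 and 321 RPKM (3.26, SE 0.22). The protein mannosyltransferases PMT3, PMT1 and PMT2 changed by 2.66 (SE 0.21), 1.90 (SE 0.25) and 1.67 (SE 0.27). Of 31 genes of the N-glycosylation list 4 rose (10 adjusted over the list alone; median 0.25, camera adjusted p = 5.2e-04, adjusted p = 0.517 with an estimated correlation), namely DPM1 (1.66, SE 0.25), KRE5, better known for cell wall beta-1,6-glucan synthesis (1.58, SE 0.31), SEC59 (1.31, SE 0.23) and ALG12 (1.22, SE 0.21). The N-glycosylation count was 2 without either vehicle library and 8 without the 40 nM inducer library, and the O-mannosylation list was no longer called without the 20 nM inducer library (adjusted p = 0.0627). KRE5 lost its call without the 20 nM inducer library, and SEC59 and ALG12 did without the 20 nM or the 40 nM vehicle library. With any 1 library left out, fold changes were 1.217 to 1.952 for KRE5, 1.142 to 1.475 for SEC59 and 1.163 to 1.273 for ALG12.

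Of 38 ER to Golgi transport genes 4 rose (15 adjusted over the list alone; median 0.61, camera adjusted p = 1.4e-05, adjusted p = 0.438 with an estimated correlation). ERV29, a cargo receptor, went from 325 and 353 to 836 and 1354 RPKM (1.65, SE 0.28). SFB2, a vesicle coat protein, changed by 1.58 (SE 0.24), RET3 by 1.12 (SE 0.20) and EMP24 by 1.00 (SE 0.20). The count was 2 without the 20 nM vehicle library, 1 without the 40 nM vehicle library, 7 without the 20 nM inducer library and 18 without the 40 nM inducer library. RET3 (adjusted p = 0.101 and 0.239) and EMP24 (adjusted p = 0.301 and 0.192) lost their calls without the 20 nM or the 40 nM vehicle library, and SFB2 without the 40 nM vehicle (adjusted p = 0.0622) or the 20 nM inducer library (adjusted p = 0.0556). Of 21 ER translocation genes 1 rose (5 adjusted over the list alone; median 0.10, camera adjusted p = 0.0739). It was SEC61, the channel subunit, at 88.5, 109, 489 and 258 RPKM (1.85, SE 0.33), with adjusted p = 0.0513 without the 20 nM inducer library. The list count was 3 without the 20 nM inducer library and 4 without the 40 nM inducer library, and the list was called without the 20 nM inducer library (adjusted p = 0.00278) and at a mean of at least 20 RPKM (adjusted p = 0.0292).

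Mating genes rose too, in cells growing vegetatively. Of 12 a-cell and alpha-cell specific genes 10 rose (11 adjusted over the list alone), with a median log2 fold change of 3.06 (camera adjusted p = 2.01e-16, adjusted p = 0.182 with an estimated correlation). Genes specific to either mating type were among them. The alpha-factor genes MF(ALPHA)2 and MF(ALPHA)1 changed by 4.24 (SE 0.30) and 4.01 (SE 0.35), the alpha-agglutinin gene SAG1 by 3.98 (SE 0.42) and AFB1, also alpha-specific, by 3.82 (SE 0.39). Of the a-specific members, named after their values were seen, the a-factor gene MFA2 changed by 3.59 (SE 0.23) and the alpha-factor receptor gene STE2 by 2.41 (SE 0.27). MF(ALPHA)2 went from 13.9 and 12.7 to 357 and 204 RPKM. Of 14 genes of the haploid pheromone pathway 8 rose (11 adjusted over the list alone; median 2.38, camera adjusted p = 5.02e-15, adjusted p = 0.182 with an estimated correlation). PRM1 and FUS1, which act in cell fusion, stood at 0.24, 0.20, 45.2 and 29.7 RPKM and at 0, 1.56, 32.6 and 27.3 RPKM. AGA1, an agglutinin anchor, changed by 4.13 (SE 0.51) and FAR1, which arrests the cell cycle, by 3.30 (SE 0.37). Without the 20 nM inducer library fewer members of each of these lists were called, and FUS1 and AFB1 were among those lost. With any 1 library left out, fold changes were 3.589 to 4.946 for FUS1 and 3.281 to 4.352 for AFB1. Repeated 50-base windows made up 14.3% of MF(ALPHA)1.

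The largest rises by fold change, at a mean of at least 10 RPKM, included genes of both kinds. ULI1, annotated to the unfolded protein response, went from 9.38 and 19.7 to 430 and 714 RPKM (5.24, SE 0.39). FIG1, a mating protein, went from 0.56 and 1.38 to 77.7 and 54.8 RPKM (5.11, SE 0.37). DOG1, a sugar phosphatase gene, changed by 4.17 (SE 0.34), with 17.5% of its windows repeated, and PEX18, a peroxisomal import gene, by 4.13 (SE 0.51). The PEX18 value, and so its place here, depends on the pseudocount, with 2.301 at 5 and 6.329 at 0.1, where its call was lost (adjusted p = 0.0585). YJL077W-B stood at 21.7 and 37.0 RPKM and YEL008C-A at 25.6 and 14.6 RPKM with inducer, and both were listed at 0 with vehicle. The values of YJL077W-B, with a coding length of 99 bases, amount to 1 and 6 reads, and its call ended with limma-voom on recovered reads (adjusted p = 0.184), an alternative chosen after seeing the data. Reads could not be recovered for YEL008C-A, which has no match in R64. PEX18 (adjusted p = 0.052) and YEL008C-A (adjusted p = 0.063) lost their calls without the 20 nM inducer library. YET2, of the list of ER shape and contact sites, went from 39.9 and 21.8 to 472 and 588 RPKM (4.11, SE 0.32), as the 1 of 17 members that rose (2 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.396). Without the 40 nM inducer library 3 members of that list rose.

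PHO84, the phosphate transporter, went from 55.0 and 45.4 to 5.95 and 3.67 RPKM (-3.16, SE 0.30). HXT4, a hexose transporter, changed by -2.63 (SE 0.38), and MPC3, of the mitochondrial pyruvate carrier, by -2.84 (SE 0.46). LEU1, of leucine synthesis, went from 1653 and 1425 to 262 and 263 RPKM (-2.54, SE 0.21), and OAC1, a mitochondrial carrier, from 1829 and 1316 to 205 and 369 RPKM (-2.49, SE 0.33). BNA1, of NAD synthesis, changed by -1.93 (SE 0.29), HOR7 by -1.94 (SE 0.21) and YEL073C by -5.08 (SE 0.55). Calls of MPC3 (adjusted p = 0.0589) and HXT4 (adjusted p = 0.0593) ended without the 20 nM inducer library, and that of HXT4 without the 40 nM vehicle library too (adjusted p = 0.109).

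Of 37 Gcn4 targets of amino acid synthesis 4 fell (7 adjusted over the list alone; median -0.31, camera adjusted p = 4.74e-04, adjusted p = 0.517 with an estimated correlation). SNZ1 and SNO1, of vitamin B6 synthesis, changed by -2.55 (SE 0.22) and -2.38 (SE 0.24), the branched-chain aminotransferase BAT1 by -1.93 (SE 0.20) and the serine synthesis gene SER3 by -1.39 (SE 0.22). The list was not called without the 40 nM inducer library (adjusted p = 0.185), where 7 members passed. SER3 lost its call without the 20 nM (adjusted p = 0.0875) or the 40 nM vehicle library (adjusted p = 0.141). Of 11 phosphate regulon genes 1, PHO84, fell (1 adjusted over the list alone, with 1 rise so adjusted; median -0.62, camera adjusted p = 0.0132, adjusted p = 0.517 with an estimated correlation). That list was not called without the 20 nM inducer library (adjusted p = 0.0517) or at a mean of at least 20 RPKM (adjusted p = 0.185), and 4 members passed without the 40 nM inducer library.

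Large housekeeping lists moved by small amounts with no member past the threshold. The ribosomal protein list, 138 genes picked by a name pattern that took in RPP1, an RNase P subunit, had a median of -0.27 (camera adjusted p = 2.34e-06, adjusted p = 0.524 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Without RPP1, an alternative chosen after seeing the data, the median was -0.273 (camera adjusted p = 1.94e-06). By dose, the list median lay at percentile 57.92 of random lists at 20 nM and 0.07 at 40 nM. Its median ratio against the other dose's vehicle library, a choice made after seeing the data, was -0.362 (20 nM) and -0.145 (40 nM). The widest values, RPL41A (-1.57) and RPL41B (-1.26), share 69.0% of their windows with other sequence. They rest on the 40 nM ratios, -2.84 and -2.49, against -0.31 and -0.03 at 20 nM. The 35 oxidative phosphorylation genes had a median of -0.37 (camera adjusted p = 1.12e-04, adjusted p = 0.517 with an estimated correlation), 0 called over all genes and 6 falls adjusted over the list alone. COX7 stood at 1486, 1830, 763 and 907 RPKM and QCR9 at 2115, 2036, 899 and 1232 RPKM. Neither list was called without the 40 nM vehicle library (adjusted p = 0.066 for each). The 19 glycolysis and fermentation genes had a median of 0.28 (camera adjusted p = 0.0463, adjusted p = 0.58 with an estimated correlation), 0 called over all genes and 1 rise adjusted over the list alone. That call ended without the 20 nM vehicle (adjusted p = 0.294), the 40 nM vehicle (adjusted p = 0.107) or the 20 nM inducer library (adjusted p = 0.666). GLK1 stood at 22.4, 19.2, 66.2 and 43.3 RPKM and CDC19 at 2336, 2576, 5896 and 3041 RPKM.

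**Figure D2:**
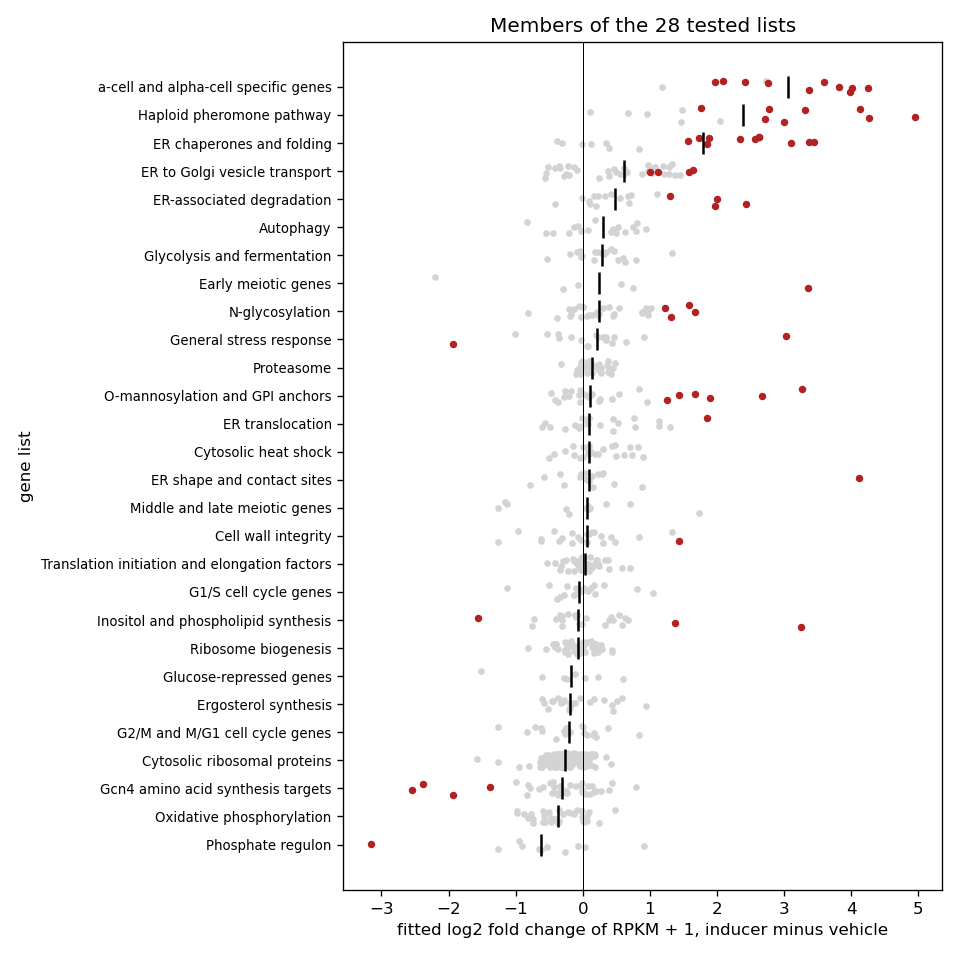
Fitted log2 fold change of RPKM + 1, inducer minus vehicle, for the members of the 28 tested lists, with red points for genes past adjusted p 0.05, grey points for the rest and black bars for list medians. The a-cell and alpha-cell list has its median at 3.06 and the ER chaperone list at 1.795.

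Of the 28 lists 16 did not pass camera after adjustment, ER translocation and ER shape among them. Inositol and phospholipid synthesis (26 genes, adjusted p = 0.56) held rises of INO1 and of OPI3, a phosphatidylcholine synthesis gene (1.37, SE 0.22), beside a fall of HNM1, the choline transporter (-1.57, SE 0.25), with the same counts adjusted over the list alone. Its median was -0.07 and its mean 0.13. OPI3 was not called without the 20 nM or the 40 nM vehicle library (adjusted p = 0.149 and 0.136), nor HNM1 without the 20 nM vehicle (adjusted p = 0.0756) or the 20 nM inducer library (adjusted p = 0.0589). Cell wall integrity (adjusted p = 0.855) held 1 rise over all genes and over the list alone, YPS1 (1.44, SE 0.25), which was not called without the 40 nM vehicle (adjusted p = 0.0681) or the 20 nM inducer library (adjusted p = 0.0592). The list itself passed without the 40 nM inducer library (adjusted p = 0.0497), where 3 members rose, and 0 rose without the 40 nM vehicle library. General stress response (adjusted p = 0.43) held 1 rise, PHM7, and 1 fall, HOR7 (2 rises and 1 fall adjusted over the list alone), and the rise was lost without the 20 nM inducer library and with median scaling (0 rises in either). Early meiotic genes (6 tested, adjusted p = 0.229) held 1 rise over all genes and over the list alone, HOP1, a meiotic chromosome axis gene, at 0.27, 0.44, 13.5 and 12.2 RPKM, lost without the 20 nM inducer library (0 rises). HOP1 and PHM7 lie outside the naming rule and were chosen after their values were seen.

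No gene passed over all tested genes in the remaining lists. Their camera adjusted p were 0.117 for autophagy, 0.14 for the proteasome, cytosolic heat shock and G2/M and M/G1 cell cycle lists, 0.342 for ribosome biogenesis, 0.56 for glucose-repressed genes and for ergosterol synthesis, 0.715 for middle and late meiotic genes, 0.769 for G1/S genes and 0.848 for translation factors. Adjusted over the list alone they held 0 calls, except 1 rise and 2 falls of middle and late meiotic genes. Without the 20 nM inducer library the proteasome list passed (adjusted p = 3.48e-06), as did the G2/M and M/G1 list (adjusted p = 0.0349). Middle and late meiotic genes had a median of 0.06 and a mean of -0.08, with CLB1 at 23.5, 26.95, 8.73 and 11.3 RPKM. With an estimated correlation camera passed 0 of the 28 lists after adjustment, against 2 with an unadjusted p under 0.05. With so few libraries it could hardly pass any, so this result weighs little against the lists. Fry, which asks whether the genes of a list move one way without comparing them with other genes, passed 6. Of the lists called by camera, it passed the a-cell and alpha-cell, pheromone, ER chaperone and O-mannosylation lists. It did not pass ER to Golgi transport or ER-associated degradation (fry adjusted p = 0.0553 each), Gcn4 targets (0.0772) or N-glycosylation (0.113). Nor did it pass oxidative phosphorylation (0.135), phosphate (0.148), ribosomal protein (0.168) or glycolysis genes (0.345).

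The comparison of doses asked whether 40 nM and 20 nM acted alike, with 1 library per dose and treatment and so without a test. Mating genes and ER chaperone genes stood high at both doses. The a-cell and alpha-cell list had a median log2 ratio of 3.18 at 20 nM and 2.97 at 40 nM, and ER chaperones 1.76 and 1.69, each at the 100th percentile of 10000 random lists. Across genes, the ratios at both doses correlated with Pearson r = 0.419 and Spearman rho = 0.289, where genes are not independent replicates. Against the other dose's vehicle library they were 0.572 and 0.442. The SD of the difference between the ratios was 0.83. Proteasome genes had a median of -0.23 at 20 nM and 0.55 at 40 nM, which lay at the 79.7th and the 100th percentile of random lists. Their median difference of 0.91 became 0.41 when each inducer library was set against the other dose's vehicle library, an alternative chosen after seeing the data. Cell wall integrity genes had medians of 0.24 and -0.38, and their median difference of -0.60 became -0.16 in that way.

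**Figure D3:**
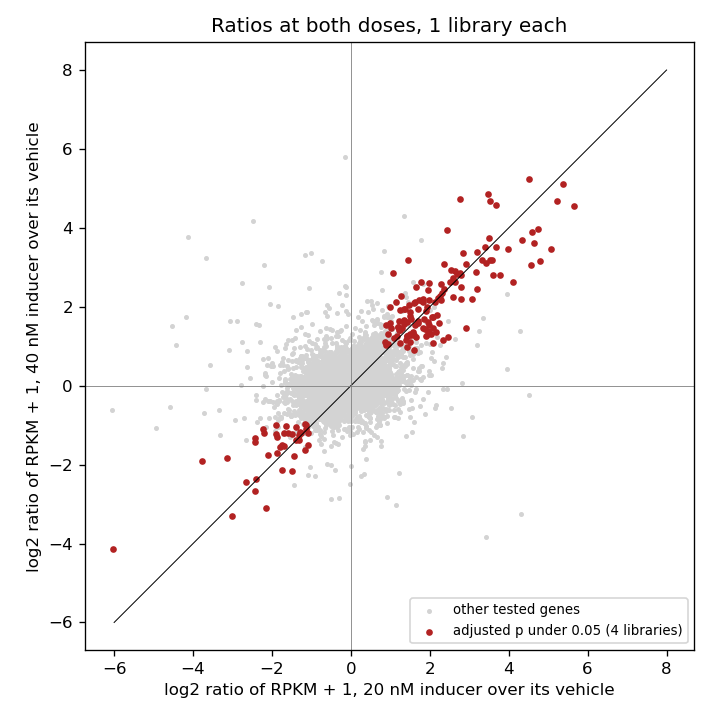
Log2 ratio of RPKM + 1 of each inducer library to its volume-matched vehicle library, 20 nM on the x axis and 40 nM on the y axis, 1 point per tested gene, with red points for adjusted p under 0.05 over all 4 libraries and a line of equality. The 171 red points have the same sign at both doses, which their separated libraries fix, and r over all points is 0.419.

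The genes with the widest difference between the dose ratios mostly rest on few reads in at least 1 library, and none was tested. Ratios were lower at 40 nM for YBR196C-B (difference -7.57), YMR158C-A (-4.75), PET191 (-4.17), COQ21 (-4.11) and CWP1 (-3.75). They were higher at 40 nM for YDR114C (6.92), THI5 (6.66), YIL066W-A (6.04), YJL047C-A (5.93) and YPR170C (5.48). In the library with fewest, recovered reads were 0 for YBR196C-B, YMR158C-A and YJL047C-A, 1 for PET191 and YDR114C, 5 for COQ21, 6 for THI5 and 7 for CWP1, so these differences depend on the pseudocount. YIL066W-A and YPR170C have no match in R64 and no recovered reads. YDR114C overlaps MRX14 and YJL047C-A overlaps SNR60, and 85.0% of the windows of THI5 are repeated. CWP1, a cell wall protein, stood at 4.97, 32.1, 10.2 and 3.64 RPKM.

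The vehicle libraries gave the background between libraries with no inducer. Their log2 ratios, 40 nM matched over 20 nM matched, had an SD of 0.43 across genes, against 0.63 for the inducer pair. Proteasome genes were lower in the 40 nM matched library, with a median of -0.25 at percentile 0 of 10000 random lists, and the ribosomal protein list higher, at 0.15 and the 100th percentile. Cell wall integrity genes had a median of 0.15 (99.9th percentile).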

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

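Tests of crossed volume labels were chosen after the result was seen, and the tests of counting noise and coding length before. Differences between doses rest on 1 library per dose and treatment and were not tested. At 20 nM and 40 nM the ratios to vehicle went opposite ways for the cell wall integrity list. Its median difference was -0.598, and -0.164 against the other dose's vehicle library. The proteasome list went opposite ways too, with medians of -0.232 and 0.552. Its 20 nM median lay at percentile 79.68 of random lists, so it was not low for genes of like level. Against the other dose's vehicle library its medians were -0.021 at 20 nM and 0.319 at 40 nM. Ratios also went opposite ways for YBR196C-B (-7.569), YMR158C-A (-4.748), PET191 (-4.169), COQ21 (-4.11) and CWP1 (-3.745), each lower at 40 nM. The same held, with higher ratios at 40 nM, for YDR114C (6.916), THI5 (6.662), YIL066W-A (6.045), YJL047C-A (5.932) and YPR170C (5.477). Of these genes, YBR196C-B, YMR158C-A and YJL047C-A had 0 recovered reads in at least 1 library, and PET191 and YDR114C had 1.

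The spread between the dose ratios as a whole was weighed. The tables argued against counting noise as the whole cause, because among 916 genes with at least 200 reads in every library, the SD of the difference was 5.62 times that of Poisson counts. A trend on coding length and level left 0.934 of the SD. Crossed volume labels in 1 group stayed open as a part of the cause. The 40 minus 20 nM differences of the vehicle pair and the inducer pair correlated at -0.205 across genes. Among genes with a mean of at least 10 and 50 RPKM they correlated at -0.273 and -0.373. Crossing would not alter the spread within a pair. Among the 916 genes the SD was 0.529 within the inducer pair, 0.199 within the vehicle pair and 0.618 for the difference, so crossing could not account for all of it. An effect of dose may also contribute and was not tested.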

How the results depend on the processing

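The use of limma-voom on recovered reads, the crossed pairing, list medians without called members, the ribosomal list without RPP1 and list counts without each library were chosen after seeing the data. Of the alternatives planned for a count table, limma-voom was run on recovered reads, and other size factors, tests and count filters were not run. Rises, 132, and falls, 39, became 243 and 123 with the volume block as replicate block, 231 and 77 with limma-voom, and 153 and 65 with median scaling. The cause was not tested, but with the volume block or the crossed pairing a common variance trend replaced each gene's own spread. Calls were 77.2% rises against 66.4% with the block and 42% without the 40 nM inducer library. Whether any numbering pairs the libraries was left open, and the crossed pairing gave 363 and 305. With dose as a number limma called 0 and 0 (344 and 146 at an unadjusted p under 0.05) and HAC1 had a slope of 3.253 (adjusted p = 0.34, against 2.79e-41 to 0.0169 elsewhere), since this coding forces the 40 nM effect to be double that at 20 nM. Leaving out each library gave 113 to 333 rises and 32 to 460 falls, with the lone sample of a group assumed to vary like the other group; without the 20 nM inducer library 112 of the 171 calls were kept. YBR196C-B ranged from -2.442 without the 20 nM vehicle library, where it is listed at 0, to 3.485 without the 40 nM vehicle library. Camera passed 0 lists with an estimated correlation, against 12, though that form could hardly pass any with so few libraries. Fry passed 6, of which 4 were among the 12. The SD of the vehicle pair was 0.274 at a mean of at least 50 RPKM, and Spearman rho was 0.442 and Pearson r 0.572 against the other dose's vehicle. Median scaling shifted fold changes by a median of -0.026. Without called members the O-mannosylation median was -0.023 and the early meiotic median -0.068. Named genes lost calls at a pseudocount of 0.1 (YEL008C-A, FUS1, PEX18, EMP24), of 5 (KRE5), with no filter (EMP24, HRD1, KRE5), with median scaling (KRE5, PHM7) and with limma-voom (YJL077W-B). The phosphate list lost its call at a mean of at least 20 RPKM and glycolysis with the volume block. ER to Golgi and ER translocation members past the threshold, 4 and 1, were 13 and 4 with the volume block, 15 and 5 with limma-voom and 8 and 2 with median scaling. N-glycosylation members, 4, were 8 with limma-voom, and cell wall integrity members, 1, were 2 with the block and with limma-voom. Fold changes of INO1, PRM1, FUS1, PEX18, YJL077W-B and YEL008C-A moved by more than 1.5 times with the pseudocount.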

Other observations

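Terms and genes in this part were chosen after the data were seen, except the tests of repeated windows, of coding length and of the counts taken by called genes. The bootstrap intervals, which resample genes and not libraries, were added after the values were seen. Some copper uptake genes fell with the inducer. Of 6 tested genes annotated to copper ion import 3 fell (adjusted p = 0.00639, hypergeometric test over 1179 terms): CTR3 at 646, 560, 119 and 224 RPKM, FET4 at 87.4, 75.6, 23.3 and 29.9 RPKM and FRE1 at 99.3, 96.9, 46.0 and 41.4 RPKM. Among rises, 11 of 49 genes of the ERAD pathway (adjusted p = 2.14e-05), 8 of 25 of pheromone signal transduction (adjusted p = 5.13e-05) and 3 of 6 with protein disulfide isomerase activity (EUG1, MPD1 and PDI1, adjusted p = 0.0419) passed. Outside the lists GFA1 and PMI40, of sugar nucleotide synthesis, rose, with GFA1 at 77.5, 75.1, 303 and 232 RPKM and PMI40 at 130, 120, 572 and 526 RPKM. GIP1, a sporulation gene, went from 2.82 and 0.93 to 19.8 and 28.5 RPKM.

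The 19 mitochondrially encoded genes tested had a median ratio of 0.92 at 20 nM, with 16 higher, and -0.30 at 40 nM, with 2 higher. With 1 poly(A) library per dose and treatment, an effect of dose cannot be told apart from a difference between library preparations. LEU2 and HIS3 were listed at 0 in all 4 libraries. So were MATALPHA1 and MATALPHA2, all of whose 50-base windows are repeated in R64 (100%), so that their 0 says nothing of their level.

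Mating genes of both types rose together. A rise in the 20 nM inducer library alone was argued against by the 40 nM ratio, whose median over the 12 a-specific and alpha-specific genes was 2.965, and shared reads by a median repeated share of 0. Pheromone signalling alone stayed open. The 8 haploid-specific genes not known to answer pheromone had a median difference of 1.214, and 6 of the 8 lay above the bound of 0.5. Its bootstrap interval over genes, 0.454 to 1.94, reached below that bound. The ends of the interval are the values of RME1 and AXL1, which both lay below the filter of 5 RPKM. Haploid cells in the inducer cultures cannot be told apart from lost repression in diploid cells, since ploidy is not in the labels. The a1 gene, whose product represses haploid genes in diploids, is listed only under HMRA1, the silent copy in R64, and reads of an active a1 copy could be counted there. That entry stood at 162, 114, 73.7 and 68.1 RPKM (difference -0.929), which may fit either.

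The ribosomal protein list, which holds RPP1, and oxidative phosphorylation genes were lower as groups in the main fit. At 20 nM the ribosomal median ratio, -0.202, lay at percentile 57.92 of random lists. Those lists could draw the ribosomal genes themselves, so this percentile cannot show whether the median was low for genes of like level. At 40 nM the median was -0.301 (percentile 0.07). Against the other dose's vehicle library the medians were -0.362 at 20 nM and -0.145 at 40 nM. Which dose stood lower thus depended on the vehicle library used. Oxidative phosphorylation genes lay at percentile 9.31 at 20 nM and 0 at 40 nM. Against the other dose's vehicle library their medians were -0.593 at 20 nM and -0.252 at 40 nM. Reads taken up by called genes, 2.71% to 2.85% of vehicle and 5.86% to 5.96% of inducer reads, were argued against: with those genes left out of the totals the ribosomal median was -0.224 (bootstrap interval -0.256 to -0.184). Coding length may account for much of the ribosomal shift, as the median after a length trend was -0.108, with an interval of -0.149 to -0.079 around the bound of -0.1. For the ribosomal list, length and inducer therefore cannot be told apart. After the same trend the oxidative phosphorylation median was -0.256 (interval -0.389 to -0.116). The camera calls of both lists ended with an estimated correlation, a form that could hardly pass any list with so few libraries. Fry did not pass either list (fry adjusted p = 0.168 for the ribosomal list and 0.135 for oxidative phosphorylation).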
